A study of Mus musculus with 4 samples.

How the data were processed

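ATF4 pull-down from heart ventricle of mice aged 4 weeks was represented by 2 samples, and input chromatin by 2 samples whose values are not analysed here. Per the labels' protocols, tissue was crosslinked with formaldehyde, sheared by sonication, precleared on protein A beads and bound to streptavidin beads. Bowtie2, MACS2, deepTools and the mouse build mm10 are named per the submitters' processing notes, with no role, order or version. Each pull-down sample had its own deposited peak list, and another list covered the series; all 3 lists were used and 0 value columns were left unmapped.

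The replicate lists give for each peak a position, a summit and a −log10 p-value or q-value, as deposited by the authors; which of the pair it is was not settled from the values. The series-wide list gives for each peak the authors' deposited fold enrichment and the offset of its summit, and was used to describe, rank and filter peaks within that list. All series-wide folds were whole multiples of 1 of a pair of steps (tolerance 0.002 of a step, 0 peaks off both), and these match (pileup + 1) divided by (background + 1) for constant backgrounds of 1.00 in replicate 1 and 1.26 in replicate 2. Peaks with identical coordinates in the series-wide and a replicate list (17420 and 21047) tied each −log10 value to a fold with no exception, and folds of replicate peaks were read from that relation; for the 4 and 5 lowest values of the replicates, which no series-wide peak matched, the steps were continued downwards. The mean ± SD (n = 2) beside a gene uses these folds, which were not scaled between samples. A fold over a constant background is not a ratio to input or to local signal. Depth per sample is unknown, and no interval for counting error of a fold is given.

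Genes were the 21900 protein-coding models of a RefSeq table of GRCm38.p6, the assembly of mm10. It gives spans without strand or exons. The planned promoter window was therefore taken as 1 kb around either end of a gene model, and exons and introns were not told apart. Motif content and the planned comparison within strata of promoter CpG content were not run, since they need genome sequence, which was not used here. Of 436 list entries all matched a symbol, 21 through an older symbol.

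Overlap of at least 1 bp was compared with 100 placements of the peaks on the same chromosome (20 for the Jaccard index), one-sided. Placement ran between the outermost peaks of each chromosome. Pairs for rank correlation joined each replicate 1 peak with the replicate 2 peak of highest value that overlapped it, with 1000 permutations of the pairing. The 21 gene lists, the rule for named genes and the tests of overlap, rank, gene features, list shares and replicate-only peaks were fixed before the data were examined; the tests of median fold and between replicates, the gene families and the tests of absent peaks were chosen afterwards. Lists were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05; shares have exact 95% intervals (Clopper-Pearson). A gene is called bound where a peak lies in the window used, which does not by itself show binding of ATF4. Median folds of bound genes were tested against 100000 random draws of as many bound genes, two-sided, for lists with at least 10 bound genes. The rule named Atf4; in each list the up to 4 members with the highest-fold peak and the first 2 in alphabetical order without one; the genes nearest the 10 peaks of highest fold; and the 5 genes with the most peaks within 10 kb per unit length among those with at least 5. The text gives a part of these, 1 of the 10 peaks is not reported here, and genes named outside the rule were chosen after their values were seen.

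Alternatives were a reciprocal overlap of 50%, the 50% of peaks with the highest values, peaks set to 200 bp, placement within 50 kb, windows of 5 kb, gene bodies with 5 kb, the 20% of peaks with the highest fold, and each replicate alone. Alternatives chosen after seeing the data were lists with peaks found in both replicates only, lists without genes on the chromosome ends that the replicate lists lack, all 49980 gene models, overlap without chromosomes M and Y, the strength test, and the McNemar test between replicates. Lengths of human chromosomes used in the closing section were entered by hand from general knowledge of the public assemblies, without a reference to check them against, and are not values of this series. Statistics were tested on simulated data over the same 21900 genes: all 10 raised lists and 0 of 100 unchanged lists were called, and the strength test called 3% of unchanged lists and 100% of lists at 2 times the fold. Simulated genes were bound independently of each other. The simulation therefore does not show how often a list of related genes would be called. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.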

Results

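Genome-wide binding of ATF4, a transcription factor of the integrated stress response, was measured in heart ventricle of mice aged 4 weeks by chromatin pull-down on streptavidin beads followed by sequencing. The antibody field of the labels of the pull-down samples reads AAV with no further explanation. The labels therefore leave open whether the ATF4 pulled down was the heart's own or came from a vector. The peaks cannot be read as binding of the heart's own ATF4 at its usual level. The labels give 2 ATF4 pull-down samples and 2 input samples, which are sheared chromatin without pull-down. The peak lists held 78746 peaks in replicate 1, 88812 in replicate 2 and 41639 in a series-wide list. The peaks covered 30.1 Mb, 33.0 Mb and 22.1 Mb, with median widths of 304 bp, 294 bp and 441 bp. Sequencing depth is unknown because the lists hold no read counts, and input values are not analysed here. The titles of the pull-down samples read ATF4-bio1 and ATF4-bio2. Bio may stand for biological replicates, but this is not explained, and the labels do not say that the samples came from separate animals. SDs between the replicates therefore measure only the spread between these samples, and how much of it is technical is not known. The p-values below count peaks or genes and measure no spread between samples or animals.

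The first comparison asked whether both pull-down samples gave the same regions. Among the 10 peaks of highest series-wide fold, all but a pair described further on had a peak in both samples. The making of the series-wide list, described below, favours such peaks. A peak inside Cd36, which encodes a fatty acid transporter (chromosome 5, 17880651 to 17881804, mm10), had a fold enrichment of 74.1 ± 6.89 (SD, n = 2). A peak inside Mylk3, which encodes a cardiac myosin light chain kinase (chromosome 8, 85379114 to 85381594), had 76.5 ± 0.304 (SD, n = 2), and a peak inside Rhobtb1 (chromosome 10, 69218487 to 69219662) had 76.3 ± 1.15 (SD, n = 2). Of the replicate 1 peaks, 63931 (81.2%) overlapped a replicate 2 peak by at least 1 bp, and 64044 (72.1%) of the replicate 2 peaks overlapped a replicate 1 peak. Random placement on the same chromosomes gave 2.68% and 2.38% on average, so the overlap was 30.3 and 30.2 times that of placement (one-sided permutation p = 0.0099 for each, the smallest that 100 placements can give). With placement kept within 50 kb of each peak the overlap was 10.9 times that of placement in both replicates. The Jaccard index of the covered bases was 0.548, against 0.00677 for placed peaks.

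Overlap depended on the strength of the peak. Among peaks under 7.5-fold, 59.8% of those of replicate 1 (95% exact interval 59.2% to 60.4%) and 45.9% of those of replicate 2 (45.4% to 46.5%) overlapped a peak of the other sample. Between 10-fold and 15-fold the shares were 97.6% and 96.2%, and at 30-fold and above all 2877 peaks of replicate 1 and all 2988 of replicate 2 had a partner. Over the 63931 overlapping pairs, Spearman's rho of the deposited peak values was 0.747 and Pearson's r was 0.899 (permutation p = 0.001, the smallest that 1000 permutations of the pairing can give). These correlations are across peaks, which are not independent replicates. The summits of paired peaks lay a median of 25 bp apart.

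**Figure D1:**
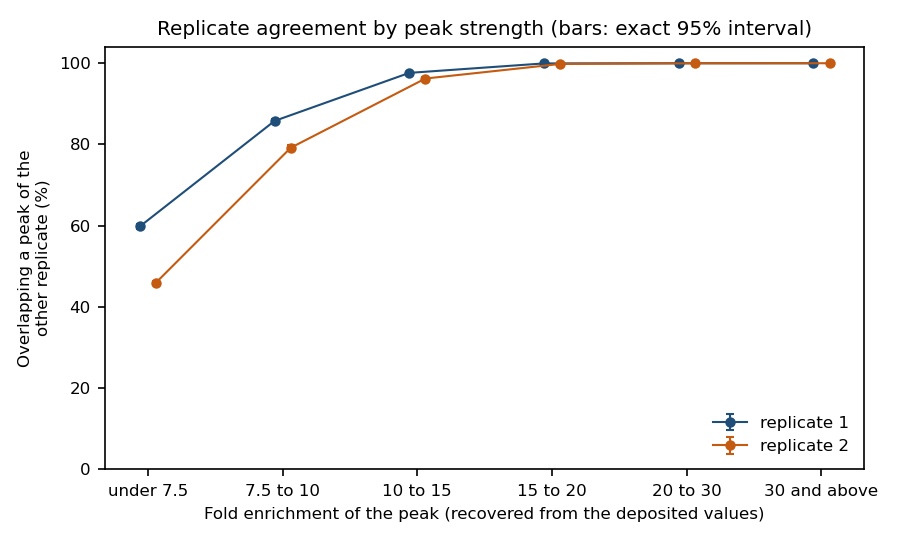
Share of peaks of each replicate (y axis, percent) that overlapped a peak of the other replicate by at least 1 bp, by fold enrichment of the peak (x axis, 6 bins); points are shares and bars exact 95% intervals, mostly smaller than the points. The share was 59.8% and 45.9% in the weakest bin and 100% in the strongest.

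The series-wide list was compared with both replicate lists. It is named as an IDR set, a kind of list that keeps peaks reproduced between replicates. A high share in both was therefore built in and is not a test of agreement. Of its 41639 peaks, 40643 (97.6%) overlapped a peak of both replicates, 1 overlapped replicate 1 alone, 2 overlapped replicate 2 alone and 993 (2.38%) overlapped neither. The share in both was 93.8% when at least 50% of the series-wide peak had to be covered by each replicate. In 40642 of the 40643 peaks found in both, the deposited fold was that of the replicate with the higher fold, so series-wide folds are the higher of a pair of values. For this reason the mean ± SD of both replicates is given beside most named genes for which both had a peak.

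**Figure D2:**
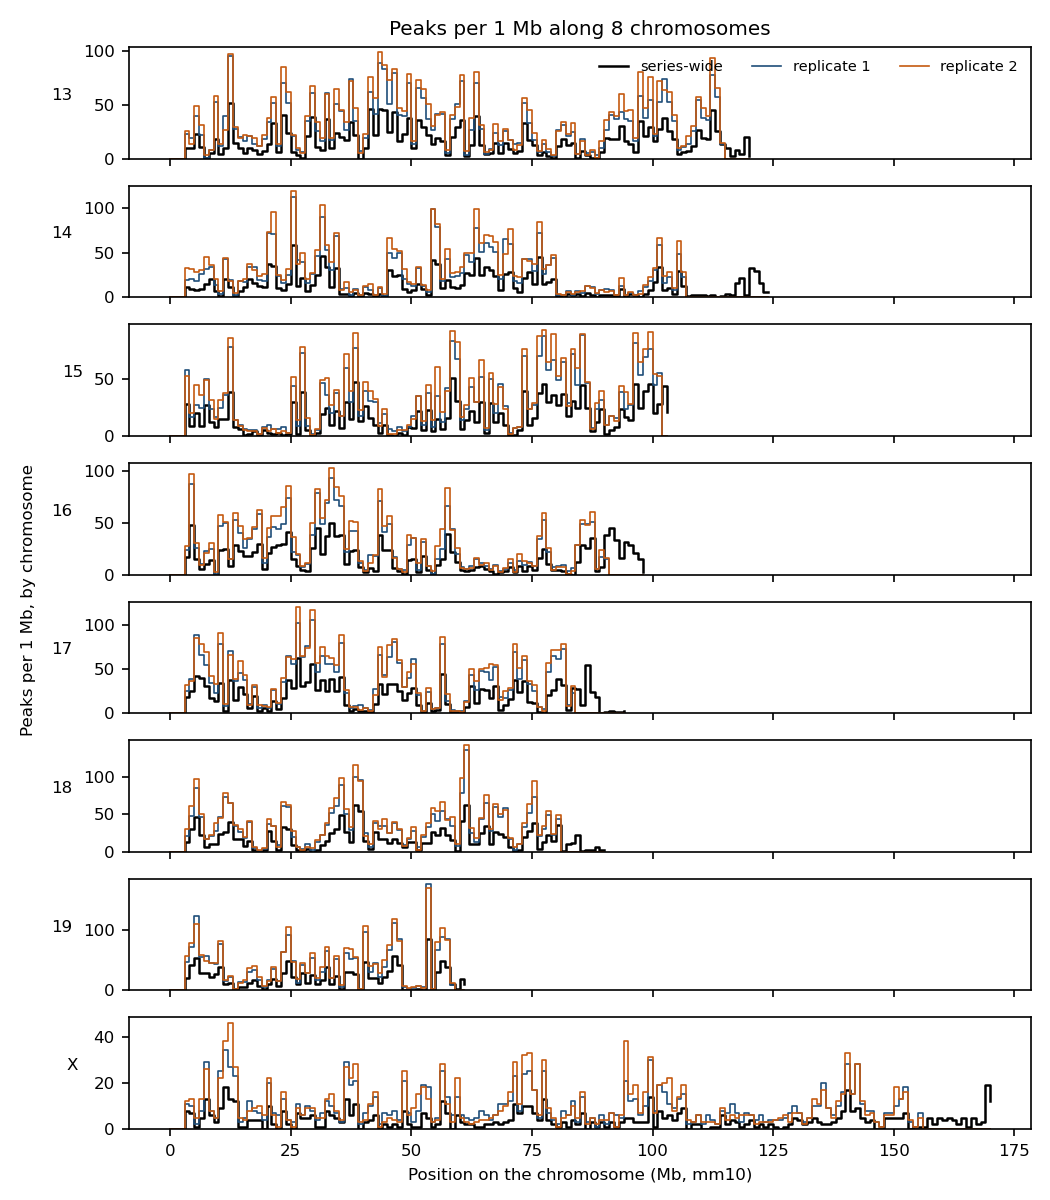
Peaks per 1 Mb (y axis) along chromosomes 13 to 19 and X (x axis, position in Mb) in the series-wide list (black), replicate 1 (blue) and replicate 2 (orange). Series-wide peaks go on past the last replicate peak, by 223 peaks on chromosome 16 and 150 on chromosome 14.

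The next question was where the peaks lay relative to genes. Peak midpoints within 1 kb of an end of a protein-coding gene made up 16.3% of the series-wide list (6807 peaks, 95% exact interval 16% to 16.7%), which was 5.22 times the share of placed peaks (3.13%). A further 47.1% lay inside gene models away from their ends, 1.2 times the placed share, and 36.6% lay outside genes, 0.633 times the placed share (one-sided permutation p = 0.0099 for each of the 3 classes, the smallest that 100 placements can give). The share near gene ends was 14.3% in replicate 1 alone and 13.8% in replicate 2 alone. The gene table used carries no strand, so a gene end here is either the start or the end of the model. With a window of 5 kb the excess over placement was 2.22 times.

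Several of the strongest peaks lay away from gene ends. The 10 peaks with the highest fold included intragenic peaks in Cd36, Rhobtb1, Mylk3 and Ypel2, a peak 21.1 kb from Cdk19, and a peak 533 kb from N6amt1, the nearest protein-coding gene. The peak in Ypel2 (chromosome 11, 86961788 to 86962569) had 69.2 ± 8.88 fold (SD, n = 2). A peak on the mitochondrial genome, deposited as positions 4 to 16348 and spanning ATP6, had 74.6 ± 3.36 fold (SD, n = 2). The folds match a constant background per replicate, so the input level of this genome was not divided out, and the value cannot be read as binding. A further pair, 25.9 kb from Col19a1 on chromosome 1 and 316 kb from Alkbh8 on chromosome 9, had series-wide folds of 78.5 and 78.0 but no peak in either replicate list. The latter was 38400 bp wide. For the same reason as at the mitochondrial genome, the values of this pair cannot be read as binding.

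Genes of the integrated stress response carried peaks throughout the list fixed for them. Here and below, bound means only that a peak lay in the window used, since input was not divided out. All 18 genes of the list of stress response regulators, which also holds downstream genes such as Fgf21, Stc2 and Vldlr, had a series-wide peak within 1 kb of a gene end, against 34.9% of other protein-coding genes (Fisher's exact test, two-sided, adjusted p = 6.13e-08). Chac1, which encodes a glutathione-degrading enzyme, had 51.1 ± 2.29 fold (SD, n = 2; peak on chromosome 2, 119350644 to 119351406). Trib3, a pseudokinase gene induced by amino acid shortage, had 45.2 ± 6.83 (SD, n = 2), Herpud1, which acts in degradation of proteins from the endoplasmic reticulum, had 45.9 ± 2.91 (SD, n = 2), and Atf3, a related transcription factor gene, had 41.1 ± 4.16 (SD, n = 2). Of 24 genes of amino acid synthesis and transport, 19 had a peak (79.2%, exact test, adjusted p = 3.06e-05). Got1, which encodes the cytosolic aspartate aminotransferase, had 69.8 ± 5.94 fold (SD, n = 2), Asns, the asparagine synthetase gene, had 32.9 ± 5.79 (SD, n = 2) and Psat1, of serine synthesis, had 32.7 ± 3.86 (SD, n = 2). Cth and Slc1a5 were among the members with no series-wide peak within 1 kb of a gene end.

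Other lists tied to protein synthesis and folding were also bound more often than other genes. Series-wide peaks lay at 16 of 21 genes of the list of cytosolic aminoacyl-tRNA synthetases, which also holds the tRNA export receptor gene Xpot (76.2%, exact test, adjusted p = 0.000236), led by Yars with 36.0 ± 2.07 fold (SD, n = 2) and Farsa with 28.6 ± 3.43 (SD, n = 2). Eprs and Hars had none in the series-wide list, but the same 20 of the 21 genes had a peak in each replicate list. The list of endoplasmic reticulum chaperones, which also holds the transcription factor gene Xbp1 and the protein degradation genes Edem1, Sel1l and Syvn1, was bound at 14 of 18 genes (exact test, adjusted p = 0.000407, and 0.131 for gene bodies with 5 kb, where the call was lost), with Creld2 at 35.5 ± 1.36 fold (SD, n = 2) and Hsp90b1 at 25.8 ± 4.52 (SD, n = 2). The list of translation initiation factors, which also holds the kinase genes Eif2ak1, Eif2ak2, Eif2ak3 and Eif2ak4, was bound at 19 of 23 genes (exact test, adjusted p = 1.52e-05), mitochondrial proteostasis genes at 13 of 14 (adjusted p = 3.06e-05) and autophagy genes at 16 of 19 (adjusted p = 3.3e-05). Hspa9, which encodes a mitochondrial chaperone, had 41.6 ± 0.551 fold (SD, n = 2), and Gabarap, of autophagosome formation, had 42.2 ± 8.04 (SD, n = 2). Genes of NADPH supply and antioxidant defence, with the ferritin genes Fth1 and Ftl1, were bound at 20 of 27 (exact test, adjusted p = 9.88e-05), with Idh2 at 22.7 ± 1.05 fold (SD, n = 2) and Hmox1 at 16.6 ± 2.91 (SD, n = 2). With the 20% of peaks of highest fold the share of this list was 3.70%, against 5.61% of other genes.

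Heart muscle genes carried peaks as well. Peaks lay at 19 of 24 genes of the sarcomere list, which also holds Des and Cryab (79.2%, exact test, adjusted p = 3.06e-05), 16 of 21 genes of cardiac transcription factors and natriuretic peptides (adjusted p = 0.000236), 13 of 19 genes of calcium handling and ion channels (adjusted p = 0.00431) and 15 of 22 genes of fatty acid oxidation (adjusted p = 0.00352). Tnnt2, the cardiac troponin T gene, had 61.1 ± 1.22 fold (SD, n = 2; peak on chromosome 1, 135835617 to 135836592), Myom2 had 56.9 ± 0.855 (SD, n = 2) and Myh6, of the alpha myosin heavy chain, had 52.6 ± 9.79 (SD, n = 2). Jph2, which encodes junctophilin 2, had 60.4 ± 0.822 fold (SD, n = 2), Mef2a had 55.1 ± 2.95 (SD, n = 2) and Gata4 had 43.6 ± 2.94 (SD, n = 2). Mef2c, Hand1, Cryab and Cpt1a had no series-wide peak within 1 kb of a gene end. Inside the gene or within 10 kb of it, Mef2c had 12 peaks, Cpt1a 5, Cryab 1 and Hand1 0.

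Housekeeping lists were also bound more often than other genes. Peaks lay at 28 of 32 ribosomal protein genes (87.5%, exact test, adjusted p = 2.26e-08), 27 of 32 genes of oxidative phosphorylation (84.4%, adjusted p = 8.07e-08) and 22 of 27 proteasome genes (81.5%, adjusted p = 4.83e-06). Ndufa9, of respiratory complex I, had 48.4 ± 0.535 fold (SD, n = 2), Psmc6 had 36.5 ± 1.44 (SD, n = 2) and Rpl8 had 32.9 ± 0.809 (SD, n = 2).

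Genes of other cell types were bound less often or did not differ from other genes. None of 19 neuronal genes had a series-wide peak (exact interval up to 17.6%, exact test, adjusted p = 0.000594). Of 15 endothelial markers 1 did (exact test, adjusted p = 0.0328), which was Tek at 8.68 ± 0.258 fold (SD, n = 2). Both calls depended on the setting. With gene bodies and 5 kb the exact test gave neuronal genes 8 of 19 (adjusted p = 0.28) and endothelial markers 10 of 15, above the 55.8% of others (adjusted p = 0.451). Endothelial markers had adjusted p = 0.139 with a 5 kb window, and 5 of 15 with adjusted p = 0.208 in replicate 2 alone, by the same exact test. The same 3 neuronal genes had a peak in each replicate list, still fewer than other genes (exact test, adjusted p = 0.00639 in replicate 1 and 0.00322 in replicate 2). Immune markers (2 of 16, exact test, adjusted p = 0.0795), fibroblast markers (6 of 15, adjusted p = 0.787), smooth muscle and pericyte markers (6 of 11, adjusted p = 0.23) and liver genes (5 of 19, adjusted p = 0.507) did not pass the test in the series-wide list. In replicate 2 alone fibroblast markers were bound more often than other genes (13 of 15, 86.7%, exact test, adjusted p = 0.00911), as were smooth muscle and pericyte markers in replicate 1 alone (9 of 11, adjusted p = 0.0385) and with a 5 kb window (adjusted p = 0.0386). Immune markers were bound less often in each replicate alone (3 of 16, exact test, adjusted p = 0.0278 in replicate 1 and 0.0143 in replicate 2), and liver genes in replicate 2 alone (5 of 19, adjusted p = 0.0446). Between the replicate lists, fibroblast markers had a peak at 8 genes in replicate 1 and 13 in replicate 2, a difference that did not pass (exact McNemar p = 0.0625, adjusted p = 0.688 over 22 lists). All 5 genes that differed had a peak in replicate 2 alone. For 5 such genes 0.0625 is the smallest p that the exact McNemar test can give, so it could not pass. Across the 21 lists, 15 were bound more often than other genes, 2 less often and 4 did not differ by the test. With the 20% of series-wide peaks of highest fold (21.5 and above), 7 lists were bound more often at the adjusted threshold; these 7 were stress response regulators, sarcomere, tRNA synthetases, cardiac transcription factors, calcium handling, ribosomal proteins and amino acid genes.

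**Figure D3:**
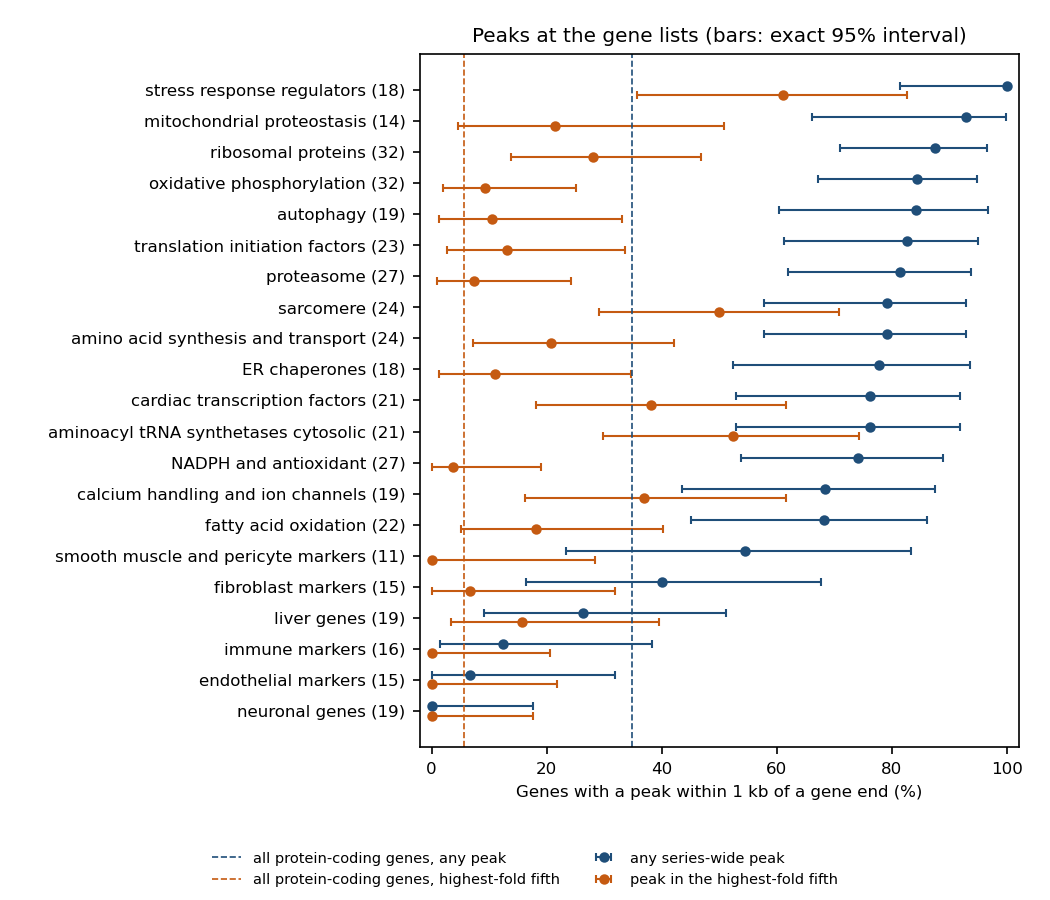
Share of genes in each of the 21 lists (number of genes in parentheses) with a peak within 1 kb of a gene end (x axis, percent), for any series-wide peak (blue) and for the 20% of peaks of highest fold (orange); bars are exact 95% intervals and dashed lines the shares of all protein-coding genes. Stress response regulators reached 100% and 61.1%, oxidative phosphorylation 84.4% and 9.38%.

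Peak strength was compared between the bound genes of each list and all bound genes; lists were not tested against each other here. The strongest peak at bound genes had a median fold of 13.3 over all 7644 bound genes, 30.6 over 19 sarcomere genes and 27.0 over 18 stress response regulators (permutation test, adjusted p = 7.5e-05 for both; the unadjusted p of 1e-05 is the smallest that 100000 permutations can give). The median was 27.0 for calcium handling genes (adjusted permutation p = 0.000187), 25 for tRNA synthetases (adjusted permutation p = 0.00015), 19.8 for cardiac transcription factors (adjusted permutation p = 0.00882) and 18.2 for amino acid genes (adjusted permutation p = 0.0227). The other 9 of the 15 lists with at least 10 bound genes did not pass, among them ribosomal proteins (14.8), proteasome (13.6), oxidative phosphorylation (12) and endoplasmic reticulum chaperones (11.3). This test was chosen after the data were seen. The median of calcium handling genes was 14 in replicate 1 alone (adjusted permutation p = 0.0352) and 11.5 in replicate 2 alone (adjusted permutation p = 0.553), and cardiac transcription factors did not pass in replicate 2 alone (adjusted permutation p = 0.0613). In replicate 1 alone ribosomal proteins (median 14.5, adjusted permutation p = 0.003) and fatty acid oxidation (15.5, adjusted permutation p = 0.005) also passed.

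**Figure D4:**
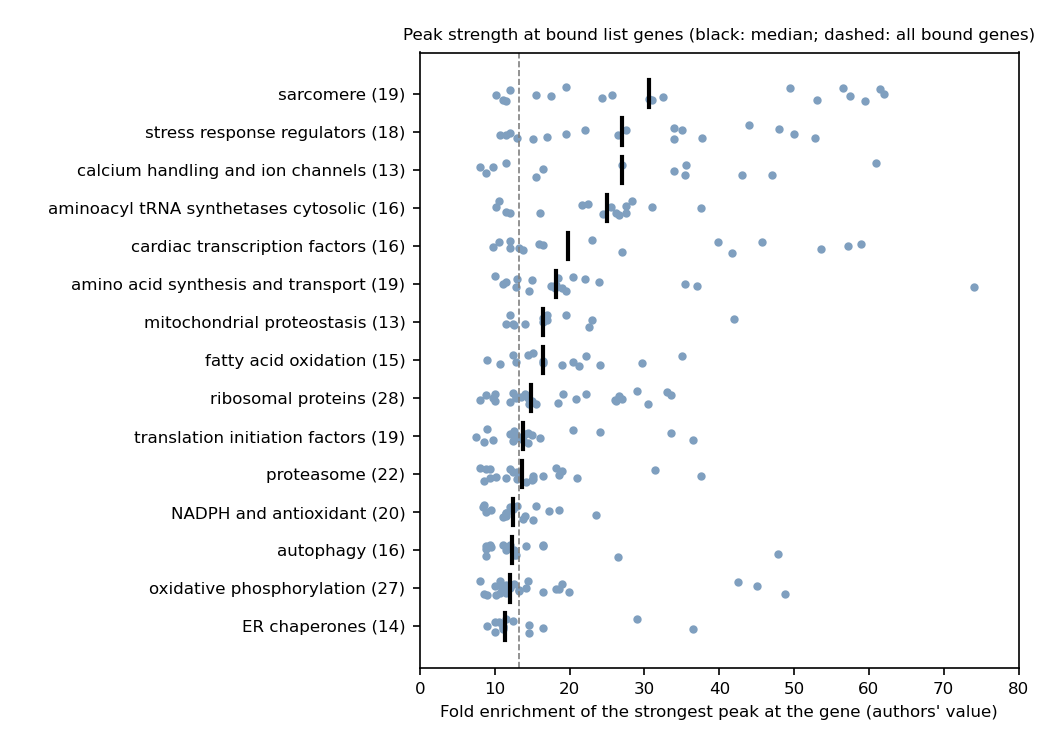
Fold enrichment of the strongest series-wide peak within 1 kb of a gene end (x axis, the authors' value), a point per bound gene, for the 15 lists with at least 10 bound genes (number in parentheses); black lines are medians and the dashed line the median of all bound genes, 13.3. Sarcomere genes had a median of 30.6 and endoplasmic reticulum chaperones 11.3.

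At Atf4 itself (chromosome 15, 80255184 to 80257545), a series-wide peak from 80254824 to 80257516 had 18.4 ± 4.75 fold (SD, n = 2). It covered 98.8% of the 2362 bp of the gene model. The peaks of replicate 1 covered 94.8% and those of replicate 2 covered 89.3%. Among 476 genes of 1500 to 3500 bp with a peak at a gene end, the median share covered was 13.9%, and 5 genes, Atf4 included, were covered at least as fully. The genes with the densest peaks were the predicted genes Gm40367, Gm40365, Gm36327 and Gm40369, which lie close together on chromosome 6, and Gm13278 on chromosome 4. Gm40367 had 49.3 ± 1.12 fold (SD, n = 2). Values at such neighbouring predicted genes are uncertain where their sequences are near-identical.

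Peaks found in a single replicate were compared with shared peaks. Shared peaks lay near gene ends more often: 15.6% of shared against 8.89% of replicate-only peaks in replicate 1 (odds ratio 1.89, Fisher's exact test, two-sided, p = 1.35e-106), and 15.6% against 9.24% in replicate 2 (odds ratio 1.81, p = 1.02e-142, the same exact test). With 50% reciprocal overlap the odds ratios were 1.21 and 1.31. Replicate-only peaks were weaker, with median folds of 6.0 and 6.21 against 9.50 and 9.75. Within bins of fold the odds ratios of replicates 1 and 2 were 1.59 and 1.58 under 7.5-fold, which holds most replicate-only peaks, 2.35 and 2.10 from 7.5-fold to 10-fold, and 2.46 and 3.66 from 10-fold to 15-fold. Peaks are not independent replicates, so these p-values describe the lists.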

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

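All tests of this part were chosen after the result was seen. The series-wide list held 993 peaks with no overlapping peak in either replicate list, a signal in regions that the replicate comparisons do not use.

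Of these peaks, 942 lay in the distal parts of chromosomes 13 to 19, X and Y, where the replicate lists held no peak at all; on chromosome 16 the last replicate peak ended at 90323288 and 223 series-wide peaks lay beyond it. They included peaks at Dnajc3 (16.5-fold) and Eif3a (9.0-fold). Weak peaks lost to a threshold are argued against, since the absent peaks had a median fold of 14.2 against 13.7 for the others. A candidate explanation is a filter that used the chromosome lengths of human GRCh38 in place of mouse lengths: 94.9% of the absent peaks lay past those lengths and 0 replicate peaks did, whereas 460 replicate peaks ended past the lengths of human GRCh37, which argues against that build. No biological explanation was tested, and the other 51 absent peaks, among them the 38400 bp region on chromosome 9, were not accounted for. These 51 had high folds, with a median of 34.6 and a highest of 78.5. Since input was not divided out, these folds cannot be read as binding. Several of the strongest lay close together on chromosome 2, between 98662178 and 98667384.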

How the results depend on the processing

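No paired analysis was possible because the input samples have no values analysed here. The alternatives below were planned unless said otherwise. Replicate overlap, rank correlation, the excess near gene ends and the comparison of replicate-only with shared peaks kept their direction and their side of the threshold under all alternatives run for them, though 50% reciprocal overlap moved the odds ratio of the last from 1.89 to 1.21 in replicate 1. With 50% reciprocal overlap the shares in the other replicate were 70.4% and 62.4%, and placement within 50 kb lowered the excess to 10.9 times. The share of series-wide peaks found in both replicates was 93.8% when 50% of the peak had to be covered, by construction a stricter demand. The making of that list favours peaks of both replicates. Lists bound more often numbered 7 with the 20% of peaks of highest fold, where fewer genes had a peak (5.61% against 34.9%), and 14 to 16 under the other alternatives. Lists bound less often numbered 2, against 1 with a 5 kb window, 0 with gene bodies and 5 kb, and 3 with each replicate alone; with the highest-fold peaks too few genes were bound for lists of this size to be called lower. With the highest-fold peaks, shares changed sides for NADPH and antioxidant genes (3.70% against 5.61% of others) and for a pair of lists that were not called in either setting, liver genes (15.8% against 5.60%) and smooth muscle and pericyte markers (0% against 5.61%); they also did for endothelial markers with gene bodies and 5 kb (66.7%, exact test, adjusted p = 0.451); the cause was not tested. The strength test, chosen after seeing the data, called 6 lists, and 4 to 8 with each replicate alone. Leaving out a replicate gave no value for overlap or rank correlation. Motif tests and CpG strata were not run for want of genome sequence used here. Unknown depth limits what absence of a peak means. A gene said to have no peak had none near its ends in the series-wide list, and can still have a peak in both replicate lists. Between 7.5-fold and 10-fold, 60.4% and 56.5% of the peaks of replicates 1 and 2 overlapped a series-wide peak.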

Other observations

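The gene families and the comparisons of strength and of replicates below were chosen after the data were seen; the motif and hepatocyte tests were written before their results were seen, the latter after the peaks at the first liver list were known. Large families of genes used in other tissues had few peaks. Of 1110 olfactory receptor genes 8 had a peak within 1 kb of a gene end (0.721%), of 355 vomeronasal receptor genes 6 did (1.69%), and of 39 genes in homeobox clusters none did (exact interval up to 9.03%), against about 35% of other genes. Mitochondrial ribosomal protein genes were bound at 60 of 78 (76.9%), with Mrps17 at 56.4 ± 0.519 fold (SD, n = 2) and Mrpl35 at 40.6 ± 0.197 (SD, n = 2). Heat shock and DnaJ genes were bound at 49 of 70 (70.0%), with Hspb2 at 53.0 ± 4.18 fold (SD, n = 2). Potassium channel genes were bound at 14 of 94 (14.9%), yet Kcnj5 and Kcnj11, which encode channels of heart muscle, had 56.0 ± 1.44 and 41.9 ± 6.55 fold (SD, n = 2).

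Strong peaks at stress response genes were weighed against the view that peak height follows only how open or transcribed a promoter is. Median fold was 27.0 at stress response regulators and 14 at 77 bound ribosomal, proteasome and oxidative phosphorylation genes (permutation p = 0.00056), but 28.8 at 32 bound sarcomere and calcium handling genes (permutation p = 0.913 against the stress genes). The first value met a bound for excluding that view, but this bound was itself written after the data were seen, so it excludes nothing. The second comparison was added afterwards. The view stays open, since openness and transcription were not measured here. Recovery of open chromatin in general also stays open as an explanation of promoter peaks: amino acid genes were bound at 79.2%, not above ribosomal (87.5%) or proteasome genes (81.5%), and the motif part of that test was not run.

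Of the 19 liver genes, 5 had peaks, and 4 of them were higher in replicate 2: Ahsg had 14 and 27.5 fold, Apoa1 10.5 and 19.9, Ttr 15.5 and 22.6. Apoa2 had 38.5 and 35. Alb, of the main plasma protein, had 14.5 ± 6.41 fold (SD, n = 2). Hepatocyte chromatin in the samples was tested as a hypothesis with 32 further hepatocyte genes, of which 1 had a peak, Pck1, against 6 of 51 genes of intestine, kidney, pancreas and testis (Fisher's exact test, two-sided, p = 0.24). The lower share met the bound set beforehand for excluding hepatocytes, but within its spread, so the counts are too few to decide: in replicate 2 alone 7 of the 32 and 6 of the 51 had a peak, and in replicate 1 alone 2 and 7.

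The peak over nearly the whole Atf4 gene model, 98.8% covered, is given as a value; the planned test of reads from an expression vector needs exon positions and was not run.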
